A study of Mus musculus with 8 samples.

How the data were processed

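Liver RNA of 4 groups of C57BL/6 mice was measured on 8 one-colour Agilent mouse arrays, 2 per group. The groups were wild-type littermates (WT) and mice with Dicer1 deleted in hepatocytes by an albumin promoter-driven Cre (KO), each given dimethylsulfoxide as vehicle or the alkylating mutagen N-ethyl-N-nitrosourea (ENU) once, at 120 mg/kg. Per the labels, mice were 6 months old, the injected volume was 2 ml/kg and treated mice were measured 15 days after ENU; the day is not given for the vehicle mice.

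Per the file headers, the deposited intensity values came from Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 10.5.1. The deposited intensity columns were the processed signal, which the program had background-corrected, and the mean signal and local background used for an alternative. Each array held 45018 spots, of which 43379 were not controls and represented 41174 probes. Probe names were updated through a RefSeq gene table of assembly GRCm38.p6: 22951 probes matched by accession, 6659 by symbol and 3084 by synonym, and 8480 kept the name in the files. Probe coordinates are those of the files, on mm7 (NCBI35).

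From these values, log2 processed signal minus each array's 75th percentile was computed. Control spots and outlier spots were left out, spots of a probe were averaged, probes had to be well above background on every array of at least 1 group, and the brightest probe stood for a gene. This left 18139 genes. Between 54.7% and 69.3% of spots per array were well above background, and no spot was saturated. The number of arrays, which counted as 4 RNA samples, limits the precision. The 75th percentile signal was 437 to 443 in WT vehicle, 504 to 524 in WT ENU and 629 to 681 in the KO arrays. Where no probe of a gene was well above background on either array of a group, the fold is a bound, which holds for this signal and scaling and not for normexp. Where another probe of the gene was, the fold is given as measured even if the probe used was dim. Scn2a, Psrc1 and Grip1 in WT are such cases. A bound compares the brighter group's mean with, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

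All 4 ENU arrays lay on 1 slide and scan and all 4 vehicle arrays on another, so slide and ENU cannot be told apart. KO and WT were compared within a slide. On both slides KO lay at positions 1 and 2 and WT at positions 3 and 4, so position and genotype cannot be told apart. The program's quality metric for negative controls was out of range on the 4 vehicle arrays and in range on the 4 ENU arrays.

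Arrays a and b of a group were compared over 157 to 183 probes spotted at least 5 times. Their median absolute standardised difference was 0.594 to 0.726, and permuting spots (2000 permutations) gave 0.694 to 0.700, with one-sided permutation p of 0.331 to 0.969, and p of 0.0935 to 0.461 for the SD of the differences. Arrays of different groups gave 12.2 to 21.7. The arrays of a group thus did not differ detectably by more than the spot noise and were counted as 1 sample, which leaves 1 RNA sample per group.

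The design fixed before the data were examined was a limma fit of 4 group means to the 8 arrays, with Benjamini-Hochberg adjustment. Given the merged arrays, that fit compares RNA samples against array noise, and not conditions, so its p-values are not printed. A second limma fit, chosen after seeing the data, used the 4 RNA samples with genotype and treatment as terms and 1 residual degree of freedom. Only this fit has samples as replicates, 2 per genotype and 2 per treatment. Its only residual is the difference between the ENU differences in KO and in WT, so a response that depends on genotype counts as noise. The words rose and fell are used for the calls of this fit at an adjusted p under 0.05. Versions were R 4.3.3 and limma 3.58.1.

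Both fits were tested on simulated data over 18139 genes with 200 changed genes. For ENU against vehicle in WT, with array noise alone, the fit of 8 arrays recovered 92.4% of genes changed by a log2 of 2 and made 6 false calls. With spread between samples added, it made 9971 false calls. For the average KO effect, the fit of 4 samples recovered 98.5% of changes of 2 log2 units, 65.7% of changes of 1 and 1.49% of changes of 0.5. It made 75 false calls beside 110 true ones, a larger share than its threshold of 0.05 allows, so its counts are approximate.

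Fixed before the data were examined were 30 gene lists and 12 cell type marker sets. In each comparison a list is described by its median log2 difference. That median's percentile was taken among 10000 random lists of the same size matched on mean expression. Random lists were drawn gene by gene, so their genes need not vary together as those of a fixed list can. A percentile thus places a list among random genes and does not test a condition. Camera was run over the 4 RNA samples with a preset correlation of 0.01 and with an estimated one. With the estimated correlation its test rests on 1 residual degree of freedom. Hardly any list could pass it, so its adjusted p-values decide nothing. The preset correlation treats the genes of a list as nearly independent. Its p-values therefore do not measure the spread between samples and decide nothing about conditions either. Named genes were, per comparison, the 10 largest increases and 10 largest decreases among symbol-named genes beyond array noise whose arrays did not overlap between groups, ranked where both groups were measured. In the averages they were the 5 largest each way. Up to 4 members per described list were named, and always Dicer1, Afp, Cdkn1a and Mgmt. Alternatives were quantile normalization, normexp background correction with an offset of 50, other filters and probe summaries, other fits, leaving out each array, and, chosen after seeing the data, median centring. Seed matches in 3 prime UTRs were not analysed here, and some genes that this rule names are not reported here.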

Results

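Liver RNA was measured in wild-type (WT) mice and in mice whose hepatocytes lacked Dicer1 (KO), after vehicle or after 1 dose of the alkylating mutagen N-ethyl-N-nitrosourea (ENU). Dicer1 encodes the ribonuclease that cuts microRNA precursors into mature microRNAs. The design asks what the loss of Dicer1 and a genotoxic exposure 15 days earlier each did to liver gene expression, and whether the response to ENU differed between the genotypes. Each of the 4 groups had 2 arrays, which did not differ detectably by more than the spot noise and were counted as 1 RNA sample. A comparison of 1 group with another therefore sets 1 RNA sample against 1, and the difference has no replicate check. The labels do not say how many mice an RNA sample represents, so p-values over the 4 RNA samples measure only the spread between these samples. That spread is how far the ENU difference in KO departs from that in WT, since no group was repeated. Below, higher and lower describe such single comparisons among 18139 genes, while rose and fell are kept for genes that passed limma over the 4 RNA samples.

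Dicer1 was lower in both KO samples than in the WT sample given the same treatment, by an amount that depended on the probe. The probe spanning 102186776 to 102188847 on chromosome 12 (mm7), a stretch longer than the probe and so a splice junction, read -1.86 in WT vehicle, -2.51 in WT ENU, -4.32 in KO vehicle and -4.02 in KO ENU, as log2 of signal over the array's 75th percentile. That is 5.51-fold lower in KO on vehicle and 2.85-fold lower after ENU. With normexp the difference of this probe, A_51_P333060, over both treatments was -1.14 log2 in place of -1.98. The other probe, at 102216485 to 102216544, was only 1.41-fold and 1.19-fold lower, and over the 4 RNA samples its difference of -0.38 ± 0.190 (SE) had a limma adjusted p of 0.196. The labels do not place the deleted exons, so it is unknown whether either probe lies within the deleted part. Of the 16 measured genes of the microRNA machinery, 3 rose and 0 fell (0 and 0 adjusted over the list alone): Ago2, the slicing Argonaute, by 1.09 log2, Drosha, the nuclear microprocessor nuclease, by 0.94, and Tnrc6a by 0.76. The list's median lay above 87.0% and 94.5% of random lists, within their central 95%. The mice are labelled female, yet probes of 4 Y-linked genes were well above background on all 8 arrays.

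**Figure D1:**
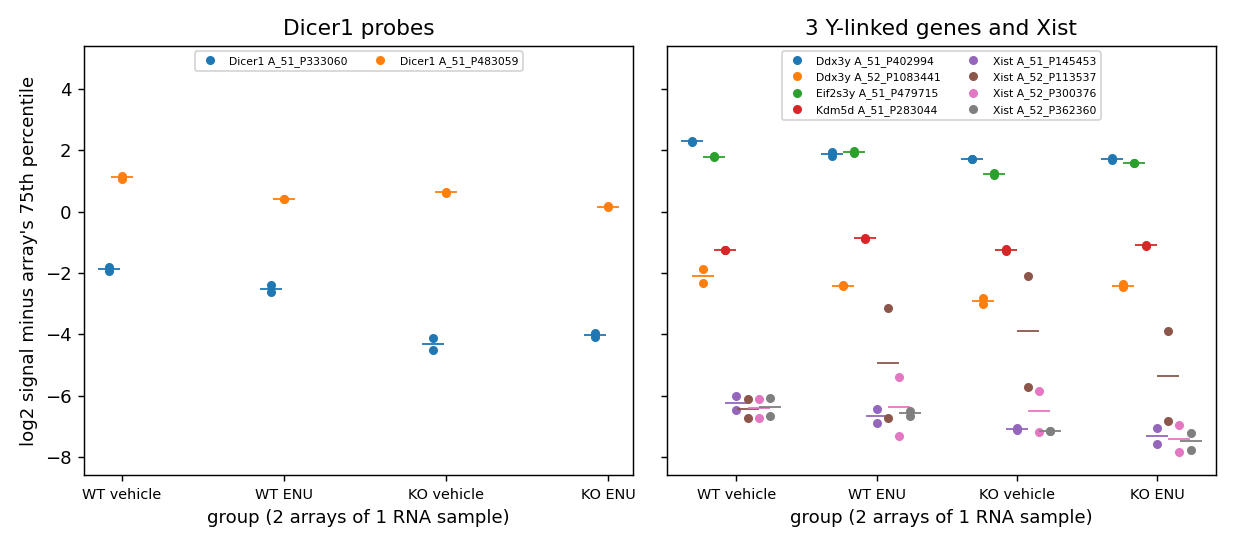
Log2 signal over each array's 75th percentile for both Dicer1 probes (left) and for probes of 3 Y-linked genes and Xist (right), with 1 point per array and a bar at the mean of the 2 arrays of each RNA sample; Uty, another Y-linked gene, is not drawn. The arrays read the Dicer1 probe A_51_P333060 at -4.50 to -3.94 in KO and at -2.62 to -1.80 in WT, and 0 of the 4 Xist probes were well above background on all arrays.

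Fetal and tumour-associated genes rose in KO liver: of 22 measured fetal and oncofetal genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 0.447 with an estimated correlation). Dlk1, a fetal hepatoblast surface protein, was 245-fold higher in KO on vehicle and 446-fold higher after ENU. Igf2, the fetal growth factor, was 125-fold and 195-fold higher, the imprinted long RNA H19 171-fold and 227-fold, and Afp, the fetal serum protein alpha-fetoprotein, 39.4-fold and 56.5-fold. Over the 4 RNA samples Dlk1 rose by 8.37 ± 0.283 log2 (SE), H19 by 7.62 ± 0.208, Igf2 by 7.28 ± 0.244 and Afp by 5.56 ± 0.223, each with a limma adjusted p of 0.00971 and higher in both pairs. Others were Ly6d, which rose by 5.94, the heparan sulfate proteoglycan Gpc3 by 5.90 and Bex4 by 5.69. Bex1 was at least 115-fold higher in KO on vehicle, where WT was not well above background. The list's median difference was 3.90 on vehicle and 4.58 after ENU (3.90 and 5.27 with dim genes at their bounds), above all 10000 random lists. In the imprinted gene list 16 of 24 rose and 2 fell (17 and 3 over the list alone; adjusted p = 0.447 with an estimated correlation). It included 3 noncoding RNAs of the Dlk1 domain: Meg3 was 56.1-fold higher on vehicle and 55.7-fold after ENU, Rian at least 79.8-fold and 248-fold, and Mirg at least 109-fold and 183-fold. Of the oncofetal genes 15 also stood in another list, and of the imprinted genes 8. Normexp gave lower folds: on vehicle 39.3-fold for Bex1, 22.5-fold for Rian and 31.3-fold for Mirg, all under their bounds, 34.4-fold for Rian and 44.8-fold for Mirg after ENU, and 26.0-fold and 33.2-fold for Gpc3. Averaging all probes gave 87.0-fold for Rian after ENU and 109-fold for Meg3 on vehicle, and without 1 of the WT ENU arrays Rian was 7.19 or 8.72 log2 units higher.

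Other genes with the largest increases in KO on vehicle were the intermediate filament gene Krt20 (155-fold), the neurotrophin receptor Ntrk2 (92.6-fold), the sodium channel Scn2a (72.8-fold) and D17H6S56E-5 (64.8-fold). In WT vehicle the Scn2a probe read -6.465, below that of Rian (-5.23), whose fold there is a bound, so 72.8-fold is not exact. After ENU the largest also included the aldose reductase relative Akr1b7 (173-fold), Wfdc3 (86.6-fold) and Grip1 (63.7-fold). In WT ENU the Grip1 probe read -6.45, below that of Psca (-5.23), whose fold there is a bound, so 63.7-fold is not exact. D17H6S56E-5 was 1.89-fold higher in KO after ENU and its adjusted p over the 4 RNA samples was 0.114. Akr1b7 rose by 6.31 ± 0.597 log2 and Krt20 by 7.95 ± 0.384 (limma adjusted p 0.0116 and 0.00971; higher in both pairs). Several of these folds depended on the processing. Scn2a on vehicle was 6.19 log2 units higher, 2.44 with normexp and 2.74 with all its probes averaged, and Ntrk2 6.53, 4.08 with normexp and 5.89 or 7.17 without 1 of the WT vehicle arrays. After ENU Grip1 was 5.99, 2.52 with normexp and 3.71 with all probes, and Wfdc3 6.44, 5.07 and 3.04. Normexp also gave 5.75 for Krt20 and 4.23 for D17H6S56E-5 on vehicle, and 6.80 for Krt20 and 6.38 for Akr1b7 after ENU, with averages of 6.28 and 5.29.

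All 26 measured G2 and mitosis genes rose in KO, over the list alone too. Cdk1, the mitotic kinase, was at least 8.20-fold higher on vehicle and 11.9-fold after ENU, its partner cyclin Ccnb1 at least 4.52-fold and 11.8-fold, the checkpoint kinase Bub1 at least 5.01-fold and 11.3-fold, and Cenpf at least 14.2-fold and 8.34-fold. The list's median difference was 3.63 on vehicle and 3.01 after ENU (3.21 and 2.99 with bounds). In DNA replication and S phase, 16 of 26 rose and 1 fell (20 and 2 over the list alone). The replication helicase subunit Mcm5 was 9.14-fold and 3.36-fold higher and Uhrf1, a partner of the maintenance DNA methyltransferase, 17.5-fold and 6.51-fold, while E2f8, a repressor of the cycle, was 6.26-fold and 17.2-fold lower. Camera gave each of the oncofetal, imprinted, mitosis and S phase lists an adjusted p = 0.447 with an estimated correlation, against 1.31e-07 or less with the preset correlation for the first 3 and 2.07e-05 for S phase. The test with an estimated correlation rests on 1 residual degree of freedom, so hardly any list could pass it. The preset test treats the genes of a list as nearly independent, so its p-values do not measure the spread between samples. With normexp the mitosis median on vehicle was 2.10, and folds on vehicle were 3.31 for Cdk1, 2.15 for Ccnb1, 2.22 for Bub1, 4.90 for Cenpf, 4.98 for Mcm5 and 2.06 log2 for Uhrf1. After ENU it gave 6.62-fold for Cdk1, 4.67-fold for Ccnb1, 3.43-fold for Bub1 and 4.94-fold for Cenpf, and with all probes averaged E2f8 was -2.29 log2.

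Cell type markers moved with genotype beside these groups. Among neutrophil and myeloid progenitor markers 13 of 14 rose and 0 fell, with the granule protein genes Mpo 11.6-fold and 34.2-fold higher and Chil3 13.2-fold and 11.2-fold. Of cholangiocyte and progenitor markers 12 of 13 rose, including the tight junction gene Cldn7 (31.0-fold and 62.6-fold higher) and Prom1 (16.9-fold and 38.5-fold). Of macrophage markers 10 of 15 rose, with Lyz2, the macrophage lysozyme, 5.08-fold and 5.31-fold higher. Among stellate cell markers 6 of 15 rose, with Pdgfrb 3.79-fold and 2.99-fold higher. Endothelial markers stood apart: 0 of 16 rose and 1 fell, with medians of 0.02 and -0.22. Matrix genes moved in the same direction as stellate markers. Of 29 extracellular matrix and fibrosis genes 25 rose and 0 fell (28 and 0 over the list alone), among them the fibrillar collagen Col1a1 (13.0-fold and 8.42-fold higher), osteopontin Spp1 (11.9-fold and 7.75-fold) and the crosslinking enzyme Loxl1 (9.52-fold and 7.21-fold). Of inflammatory cytokines and chemokines 16 of 20 rose, led by the monocyte attractant Ccl2, 49.6-fold higher on vehicle and 11.1-fold after ENU. Of 9 MHC class II genes 8 rose, with H2-Ab1 4.10-fold and 4.39-fold higher. Adjusted over the list alone, 13 neutrophil, 12 cholangiocyte, 11 macrophage and 8 stellate markers, 16 cytokine and 8 MHC class II genes rose, 1 macrophage marker fell, and 0 endothelial markers passed. Each of these lists except the endothelial one, for which it was 0.915, had an adjusted p = 0.447 with an estimated correlation. With normexp Prom1 was 3.78-fold and 16.5-fold higher, Mpo 5.50-fold and 12.7-fold, Chil3 6.85-fold and 7.17-fold, Cldn7 16.8-fold and 31.9-fold, and on vehicle Ccl2 27.4-fold and Loxl1 5.67-fold; with quantile normalization Lyz2 was 8.28-fold higher after ENU.

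Many genes of the adult hepatocyte fell in KO. Of 23 mature hepatocyte genes 14 fell and 0 rose (21 and 0 over the list alone), such as the tryptophan-degrading enzyme Tdo2 (3.58-fold lower on vehicle, 6.14-fold after ENU) and the asialoglycoprotein receptor subunit Asgr1 (2.84-fold and 4.07-fold). In bile acid synthesis and transport 12 of 20 fell and 2 rose, over the list alone too. The bile acid hydroxylases Cyp7b1 and Cyp27a1 were 49.6-fold and 8.26-fold lower on vehicle, and the basolateral exporter subunit Slc51b was at least 8.29-fold higher. Of 21 fatty acid synthesis genes 11 fell and 0 rose (13 and 0 over the list alone). Thrsp, a regulator of lipogenesis, was 25.4-fold and 21.4-fold lower, the carboxylase Acacb 4.93-fold and 14.5-fold, and the desaturase Scd1 4.80-fold and 8.07-fold. Of 25 fatty acid oxidation genes 12 fell and 1, Acot2, rose (14 and 1 over the list alone); the P450 Cyp4a10 was 3.94-fold and 3.73-fold lower. Among pericentral hepatocyte genes 12 of 20 fell and 3 rose (13 and 4 over the list alone), with the glutamate transporter Slc1a2 8.79-fold and 8.86-fold lower, and among periportal genes 7 of 20 fell and 1 rose (11 and 1). Of 22 cholesterol synthesis genes 5 fell and 0 rose, over the list alone too. Their median was -1.54 after ENU, below all random lists, and on vehicle it was 0.08, above 99.6% of them, turning to -0.07 when all probes of a gene were averaged and to -0.15 with median centring. Among random lists matched on expression, the medians of the bile acid and fatty acid synthesis lists lay below all 10000 in both pairs and that of pericentral genes at percentile 0.01 in both. The mature hepatocyte median lay at percentile 0.73 on vehicle and at 4.24, inside the central 95%, after ENU. In both pairs the oxidation list (4.44 and 14.1) and the periportal list (33.6 and 6.11) also lay inside, so their medians were no lower than those of many lists of similar expression. With quantile normalization the mature hepatocyte median was -0.26 on vehicle and -0.34 after ENU, and on vehicle Tdo2 differed by -1.21 log2, Asgr1 by -0.81, Scd1 by -1.61 and Cyp4a10 by -1.31, and after ENU Asgr1 by -1.43; with normexp Slc51b on vehicle differed by 1.76. The adjusted p was 0.447 with an estimated correlation for the mature hepatocyte, bile acid, oxidation, pericentral and periportal lists, 0.519 for fatty acid synthesis and 0.708 for cholesterol synthesis.

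Sex-dependent liver genes moved apart in KO. The mice are labelled female, yet probes of 4 Y-linked genes were well above background on all 8 arrays, so the sex of the tissue is in doubt. All 19 measured male-predominant genes fell in KO, over the list alone too: the steroid dehydrogenase Hsd3b5 was 103-fold lower on vehicle and 834-fold after ENU, the organic anion transporter Slco1a1 81.8-fold and 687-fold, and the fatty acid elongase Elovl3 138-fold and at least 1051-fold. Hsd3b4, a close relative whose probe may not separate it from Hsd3b5, was 49.7-fold and 164-fold lower, and the sulfotransferase Sult2a8 41.0-fold and 71.7-fold. Over the 4 RNA samples Hsd3b5 fell by 8.20 ± 0.783 log2, Slco1a1 by 7.89 ± 0.797, Hsd3b4 by 6.50 ± 0.472, Sult2a8 by 5.76 ± 0.272 and Cyp7b1 by 5.53 ± 0.187, with limma adjusted p between 0.00971 and 0.0124 and lower in both pairs. Other large decreases on vehicle were Atp12a (28.3-fold), Defb19 (23.3-fold) and Serpina4-ps1 (22.7-fold; 84.9-fold after ENU). After ENU the largest also included Cyp4a12a (104-fold), Sdr9c7 (77.9-fold) and Nat8f5 (52.2-fold). Of 19 female-predominant genes 9 rose and 0 fell, over the list alone too. The transcription factor Cux2 was at least 8.47-fold and 15.9-fold higher, A1bg at least 9.78-fold and 8.10-fold, and the cytochrome P450 Cyp2b9 8.72-fold and 26.3-fold. With an estimated correlation the adjusted p was 0.447 for the male-predominant and 0.559 for the female-predominant list. Normexp gave 64.5-fold and 234-fold for Elovl3, the latter under the bound, and 61.5-fold and 376-fold for Hsd3b5. It made the decreases of Slco1a1 -5.06 on vehicle and -6.35 after ENU, of Sdr9c7 -3.77 after ENU, of Serpina4-ps1 -3.91 and -4.89, of Atp12a -3.23 on vehicle and of Defb19 -3.46 on vehicle, and the increases of Cux2 1.73 and 2.30 and of A1bg 1.99 and 1.57. Leaving out 1 of the KO arrays gave -5.42 or -7.29 for Slco1a1 on vehicle and -8.43 or -10.41 after ENU, and with all probes averaged Slco1a1 was -7.48 on vehicle, Serpina4-ps1 -7.18 after ENU and Cyp4a12a 55.4-fold lower after ENU. In KO ENU the mean of Slco1a1 (-6.18) lay below that of Elovl3 (-6.15), whose fold there is a bound, so 687-fold is not exact. The average differences with normexp were -7.25 for Hsd3b5 and -5.70 for Slco1a1.

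Genes reported as targets of hepatocyte microRNAs rose in part. Of 20 reported targets of miR-122, an abundant hepatocyte microRNA, 12 rose and 0 fell (14 and 0 over the list alone): Gpx7 was 6.59-fold and 11.7-fold higher, Klf6 6.72-fold and 6.30-fold, and Cers6 2.71-fold and 6.00-fold. Of 19 reported let-7 targets 9 rose and 0 fell (9 and 1 over the list alone), with the RNA-binding protein gene Igf2bp3 20.6-fold and 4.24-fold higher, Arid3a 9.71-fold and 9.23-fold, and cyclin D1 (Ccnd1) 9.77-fold and 5.37-fold. In each list 7 genes also stood in another list, and both had an adjusted p = 0.447 with an estimated correlation. Of 29 p53 targets 10 rose and 2 fell (11 and 3 over the list alone; adjusted p = 0.447 with an estimated correlation), led by Psrc1 (39.6-fold and 16.3-fold higher) and Pmaip1, which encodes the apoptosis activator Noxa (9.43-fold and 4.37-fold). Cdkn1a, the p53-induced cell cycle inhibitor, was not among them, at -0.48 on vehicle and 0.77 after ENU (limma adjusted p 0.78). Of 31 DNA repair genes 7 rose and 0 fell (2 and 0 over the list alone; medians at percentiles 72.7 and 62.3 among random lists), with Brca1, of homologous recombination repair, 2.18-fold and 4.01-fold higher. Mgmt, the alkyltransferase that removes alkyl groups from guanine, was 1.45-fold and 2.59-fold lower and did not pass (-0.95 ± 0.278, adjusted p 0.0698). With normexp Igf2bp3 was 5.64-fold higher on vehicle, Arid3a 6.42-fold and 5.31-fold, Pmaip1 4.45-fold and 2.77-fold, and Psrc1 4.75-fold and 9.26-fold (9.10-fold and 9.88-fold with all probes averaged). The 39.6-fold of Psrc1 on vehicle is not exact. Its probe read -5.78 in WT vehicle, below that of Rian (-5.23), whose fold there is a bound.

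Over the 4 RNA samples limma called 5844 genes for genotype at an adjusted p under 0.05, of which 3064 rose and 2780 fell, and 8779 had an unadjusted p under 0.05. On vehicle 3028 genes were at least 2-fold higher and 1927 lower beyond array noise, and after ENU 2816 and 2508. The 2 pairs each lay within 1 slide and shared no array. Their differences correlated across genes with a Pearson r of 0.836 and a Spearman rho of 0.808. Genes are not independent replicates. Each genotype held the same positions on both slides, so a position effect would repeat in both pairs. At least 2-fold in both pairs, 2252 genes were higher (470 by chance) and 1340 lower (266 by chance), and 30 went opposite ways. Increases made up 52.4% of the calls of the average KO effect over 4 RNA samples, 58.5% after quantile normalization, 35.9% after median centring, 36.5% after normexp and 36.6% where probes had to be above background on all arrays. The median of all genes was -0.14 and -0.10 in the 2 pairs, and -0.37 and -0.28 with median centring.

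**Figure D2:**
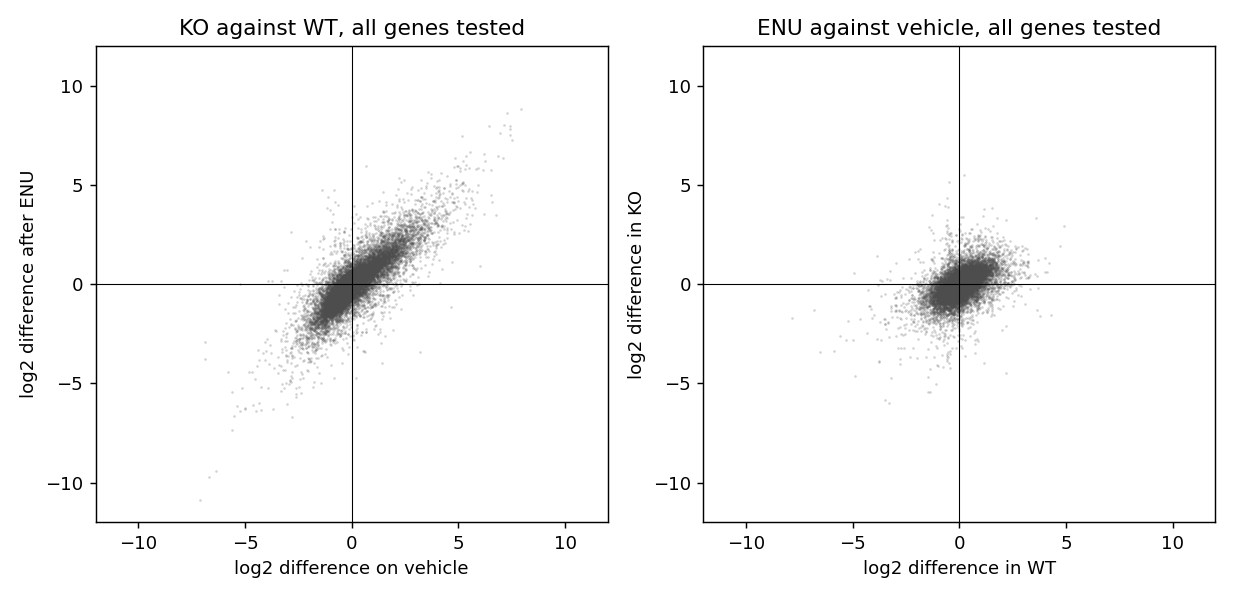
Each point is 1 of the 18139 genes, with its measured log2 difference of KO against WT on vehicle and after ENU (left) and of ENU against vehicle in WT and in KO (right); genes not well above background in 1 of the groups are drawn at their measured values. The genotype differences correlated at r = 0.836, and the ENU differences, whose samples share the same pair of slides, at r = 0.504.

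In WT liver 15 days after ENU, the lists of lipid storage, fat oxidation and clock genes had negative medians, and those of cell cycle, interferon and cholesterol synthesis genes positive ones. Of 18 clock genes 13 were at least 2-fold lower, while Arntl was higher by 1.42 log2, Nr1d1 by 1.78 (0.92 with all probes averaged) and Npas2 by 1.47 (0.02 with normexp, and not well above background in WT vehicle); in KO 6 were lower and 1, Nr1d1, higher. The largest decreases were Mfsd2a, a lysophospholipid transporter (94.1-fold), Hamp2, a hepcidin (49.1-fold), the clock output gene Usp2 (40.6-fold), the lipid droplet coats Plin4 (31.6-fold) and Cidec (29.7-fold), and Ppp1r3g, a glycogen-targeting subunit (30.4-fold). Myom1, Cfd, Cgref1 and Cyp4a14 were 25.4-fold, 18.4-fold, 15.9-fold and 14.7-fold lower. The largest increases were Cyp26a1, the retinoic acid hydroxylase (17.3-fold), heparanase Hpse (11.5-fold), Xlr3c (3.33 log2), the activin antagonist Fst (9.23-fold), Tmem218 (9.12-fold), Wdr86 (8.72-fold), the water channel Aqp8 (8.40-fold), Psrc1 (7.93-fold), Ncald (7.77-fold) and the interferon-induced GTPase Ifi47 (7.63-fold). The fold and rank of Psrc1 are not exact. Its probe read -5.78 in WT vehicle, below that of Rian (-5.23), whose fold there is a bound. Beyond array noise, 1205 genes were at least 2-fold higher and 901 lower. Several of these differences shrank with normexp: Psrc1 to 0.64 log2 (1.40 with all probes averaged), Hpse to 1.76, Fst to 1.82, Xlr3c to 2.51, Hamp2 to -3.67 and Myom1 to -2.61 (-3.73 with all probes averaged), Usp2 to 18.9-fold, Cfd to 9.26-fold, Mfsd2a to -5.94, Ppp1r3g to -4.16, Cgref1 to -3.12 and Ncald to 2.27.

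In KO liver after ENU, renin and serum amyloid genes had the largest decreases. Ren1 and Ren2, whose probes may not separate these near-identical genes, were 63.0-fold and 57.9-fold lower, and the serum amyloid genes Saa1, Saa2 and Saa3 43.3-fold, 43.1-fold and 33.0-fold. The fasting hormone Fgf21 was 26.9-fold lower, Cidec 24.4-fold, Ctcflos 16.5-fold and D17H6S56E-5 15.6-fold. The clock repressor Nr1d1 was 3.33 log2 units higher, 2 immunoglobulin kappa variable segments, Igkv4-55 among them, 6.31-fold and 5.96-fold, the neurotrophin receptor Ngfr 5.97-fold, the cold-inducible Cirbp 5.21-fold, Adgrf1 5.17-fold, Myl7 5.11-fold, Psca 5.05-fold, Ccl21c 4.88-fold and Prom1 4.87-fold. At least 2-fold, 686 genes were higher and 893 lower. Nr1d1 was only 1.83 with normexp and 1.22 with all probes averaged, and normexp gave 1.47 and 1.94 for the 2 kappa segments, 1.12 for Adgrf1, 1.15 for Myl7, -2.77 for Fgf21 and -2.81 for Ctcflos. Without 1 of the KO vehicle arrays Myl7 was 1.75 or 2.96.

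Several gene lists lay outside all random lists after ENU in both genotypes. This does not test ENU, since a list whose genes vary together can lie outside whenever 2 RNA samples differ. Of 25 fatty acid oxidation genes 13 were at least 2-fold lower in WT and 12 in KO, and 0 were higher. Fgf21 was 9.35-fold and 26.9-fold lower, the peroxisome gene Pex11a 6.70-fold and 5.69-fold, and Cpt1a, which admits fatty acids to mitochondria, 3.05-fold and 4.69-fold. The WT ENU arrays of Fgf21 differed widely (SD 1.65 log2), so its 9.35-fold is imprecise. Of 14 lipid droplet genes 7 were lower in WT and 10 in KO, 1 was higher in KO, and Plin5 was 6.04-fold and 4.23-fold lower. Beside both groups the 4 measured adipocyte markers had medians of -1.63 in WT and -1.02 in KO, at percentiles 0.01 and 0.43 among random lists, and 3 of the 4 were lower over the 4 RNA samples at an adjusted p under 0.05 over the list alone. Of 21 heat shock genes 9 and 7 were lower, including the inducible chaperone Hspa1a (4.97-fold and 12.8-fold). In the G2 and mitosis list 22 of 26 genes were at least 2-fold higher in WT and 13 in KO, with medians of 1.59 and 1.03 (1.42 and 1.03 with bounds); the anaphase activator Cdc20 was 7.34-fold and 2.29-fold higher and Nusap1 5.39-fold and 2.59-fold. For S phase the numbers were 13 and 6 of 26, with Mcm5 5.96-fold and 2.19-fold higher. Of 33 interferon response genes 17 and 6 were higher, among them Gbp6 (7.04-fold and 2.05-fold) and the T cell attractant Cxcl9 (4.06-fold and 2.87-fold). Beside them, medians of macrophage markers were 0.86 and 0.68, of natural killer markers 0.99 and 0.73, and of MHC class II genes 0.91 and 0.75. Stellate marker medians (0.43 and 0.45) also lay above the central 95% of random lists in both genotypes. Those of T cell (0.57 and 0.43), B cell (0.67 and 0.55) and cholangiocyte markers (0.45 and 0.40) did so as measured, but with dim genes at their bounds the WT medians of T cell (0.17), B cell (0.12), cholangiocyte (0.23) and natural killer markers (0.56) lay inside, and with normexp the B cell median in WT was -0.12. Granzyme B (Gzmb) was 4.27-fold and 3.21-fold higher. Normexp lowered the mitosis medians to 0.68 and 0.84, and in WT Nusap1 to 0.81 log2, Mcm5 to 3.51-fold, Cdc20 to 4.10-fold, Gzmb to 2.14-fold and the decrease of Fgf21 to -2.00, and in KO that of Fgf21 to -2.77.

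Among genes known to answer DNA damage a minority differed at least 2-fold. Of 29 p53 targets 5 were at least 2-fold higher and 3 lower in WT, and 4 and 2 in KO, with medians of 0.21 and 0.26, above 98.0% and 99.8% of random lists (0.18 and 0.24 with bounds, the first inside their central 95%). Psrc1, whose probe was dim in WT vehicle, was 7.93-fold and 3.26-fold higher, and Ckap2 4.16-fold and 2.99-fold. With normexp in WT they were 1.56-fold and 1.25-fold higher. Eda2r, counted as higher in WT, was not well above background in either WT group and differed by -0.18 with normexp. Cdkn1a was 2.11-fold lower in WT and 1.13-fold higher in KO after ENU, while Phlda3, a p53-induced inhibitor of Akt signalling, was 3.71-fold and 1.65-fold higher. In DNA repair the medians were 0.32 and 0.22, above 99.6% and 99.3% of random lists, with 1 of 31 genes at least 2-fold higher in each genotype and 1 lower in WT. Mgmt was 1.27-fold higher in WT and 1.40-fold lower in KO.

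Over the 4 RNA samples limma called 0 genes for ENU after adjustment, with 3992 at an unadjusted p under 0.05. Where the ENU differences in WT and KO were unlike, this fit counts that as spread, so such genes could hardly pass. Cidec (-4.75, unadjusted p 2.01e-05; lower in both pairs), Mfsd2a (-4.98), Ren2 (-4.67), Ren1 (-4.64) and Hamp2 (-4.12) had the largest decreases and Nr1d1 (2.55), Cyp26a1 (2.36), Psrc1 (2.35), Ifi47 (2.30) and the eotaxin receptor Ccr3 (2.27) the largest increases. Normexp lowered the average difference of Psrc1 to 1.12, of Ccr3 to 1.17, of Nr1d1 to 1.55 and of Hamp2 to -2.91, and with all probes averaged Nr1d1 was 1.07 and Psrc1 1.46. With p-values adjusted over the list alone, 24 of 26 mitosis genes, 18 of 26 S phase genes and 19 of 33 interferon genes were higher at an adjusted p under 0.05, and 19 of 25 fatty acid oxidation genes, 9 of 14 lipid droplet genes and 8 of 21 heat shock genes lower, against 0 of each over all genes. Camera called 25 of 42 lists with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.619 with an estimated correlation). The latter count decides nothing, since that test rests on 1 residual degree of freedom and hardly any list could pass it. The former count decides nothing about ENU either, since the preset of 0.01 treats genes as nearly independent. Estimated correlations ranged from -0.333 for adipocyte markers to 0.818 for cholesterol synthesis. All ENU arrays lay on 1 slide and all vehicle arrays on another, so slide and ENU cannot be told apart. Across genes the ENU differences in WT and KO correlated at r = 0.504 (rho 0.543), with 296 genes higher in both (45.6 by chance) and 304 lower (44.4 by chance).

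The response to ENU differed between the KO and WT samples for clock, cholesterol synthesis and serum amyloid genes. The glycogen gene Ppp1r3g was 30.4-fold lower after ENU in WT and 1.48-fold higher in KO, a log2 difference between the responses of 5.49. Clock genes followed: Dbp was 12.5-fold lower in WT and 1.13-fold higher in KO (3.82), Per1 12.8-fold and 1.53-fold lower (3.06), and Usp2 40.6-fold and 7.05-fold lower (2.52). The clock list's median was -1.41 in WT and -0.45 in KO, and its interaction median was 0.96. Tiam2 (3.93), Mfsd2a (3.16), Hamp2 (2.99), Myom1 (2.89), Krt23 (2.79) and Osbpl3 (2.54) also had less negative or more positive responses in KO. Responses were more negative in KO for D17H6S56E-5 (-5.10), Prelid2 (-4.30), Saa2 (-4.07), Saa1 (-3.95), Saa3 (-3.92), Cyp4a12a (-3.88), the prostaglandin synthase Ptgds (-3.76), Cyp26a1 (-3.52), Syt10 (-3.35) and Slc41a2 (-3.32). Of 22 cholesterol synthesis genes 15 were at least 2-fold higher after ENU in WT and 1 in KO. Hmgcs1, which makes the HMG-CoA of the pathway, was 6.27-fold higher in WT and 1.15-fold lower in KO, and Msmo1 4.62-fold and 1.04-fold higher; the list's interaction median was -1.40. Beyond array noise, 574 genes had a response at least 2-fold more positive and 940 more negative in KO. With 1 RNA sample per group these differences of differences have no test between samples. They also depended on the processing. Normexp gave 1.63 for Tiam2, 1.52 for Hamp2, 1.495 for Myom1, 1.07 for Osbpl3, 1.91 for Usp2 and 4.75 for Ppp1r3g. It gave -3.51 for D17H6S56E-5, -3.64 for Prelid2 and -3.14 for Ptgds. With all probes averaged Cyp4a12a was -3.19.

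**Figure D3:**
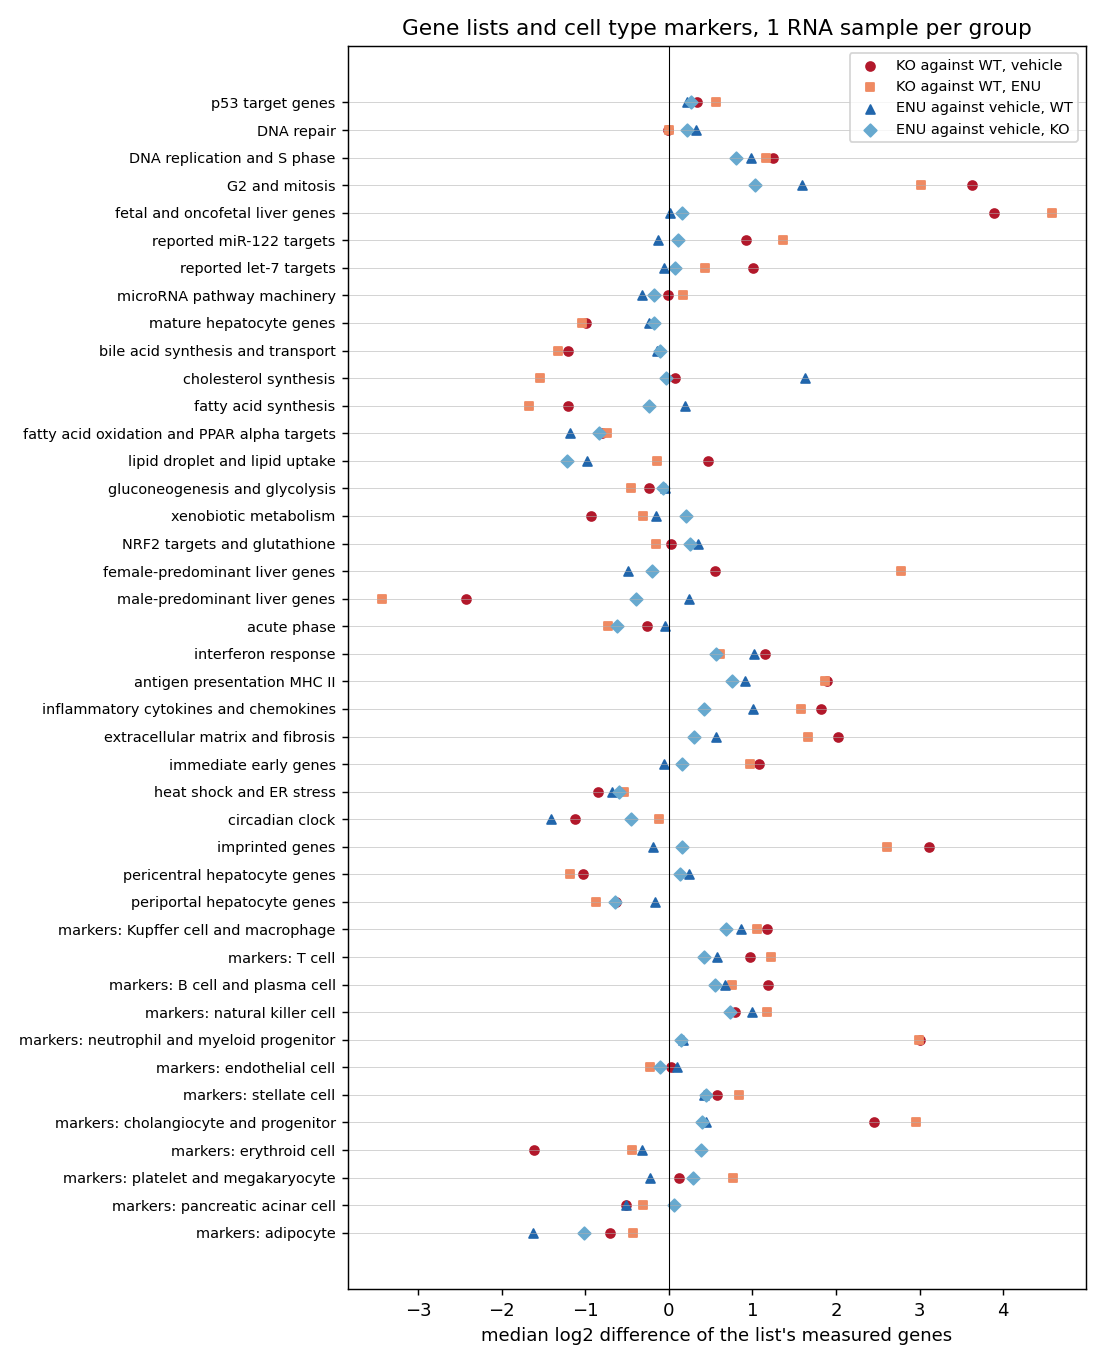
Median log2 difference of the measured members of 30 gene lists and 12 cell type marker sets, with 1 symbol per comparison of 1 RNA sample with another (circles and squares, KO against WT on vehicle and after ENU; triangles and diamonds, ENU against vehicle in WT and in KO). G2 and mitosis genes had medians of 3.63 and 3.01 for genotype and of 1.59 and 1.03 for ENU, while male-predominant genes had medians of -2.42 and -3.43 for genotype and of 0.24 and -0.39 for ENU.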

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

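All tests of explanations in this part were chosen after the results were seen.

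Mitosis and oncofetal genes were higher in both KO samples. With quantile normalization and median centring, the lowest median of the G2 and mitosis list over both pairs was 2.83, above the bound of 1. On vehicle the median of all genes was -0.14 as scaled, -0.08 with quantile normalization and -0.37 with median centring. Beside list medians of 3.63 and 3.01, a fall under 1 could hardly occur, so this bound decides little. The mitosis genes stayed higher under both scalings, and the oncofetal genes were not part of this test. A lower share of hepatocytes alone would raise the markers of every other cell type alike, and the neutrophil marker median lay above the endothelial one by at least 2.98 in each pair. A lower share together with unequal changes of the other cell types would give such a gap too, so the gap cannot speak against it. A change in other cell types stays open, since neutrophil, cholangiocyte and macrophage markers rose too. An effect of Dicer1 loss within hepatocytes was not tested and stays open too.

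The medians of clock and fatty acid oxidation genes were negative for ENU against vehicle, with 3 of 18 clock genes at least 2-fold higher in WT. An additive effect of slide or scan on the clock genes would be the same in both genotypes. Their interaction median was 0.96, outside the random lists (-0.27 to 0.23). Random lists need not vary together as clock genes can, and each group holds 1 RNA sample. The gap therefore does not exclude such an effect. For fatty acid oxidation the interaction median was 0.08, so an additive slide effect on these genes cannot be told apart from ENU. Arntl, whose transcript peaks opposite to Per1, Per2 and Dbp, was higher by 1.42 log2 after ENU in WT, as another time of day of collection would give; Nr1d1, not part of this test, was higher in both genotypes (1.78 and 3.33). Collection times are not given in the sources used here, so time of day, or a time of day that also differed between genotypes, and ENU cannot be told apart.

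Transcripts of Y-linked genes appeared in samples labelled female: 5 probes of Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on all 8 arrays. Among all genes of an array, Ddx3y lay at percentiles 75.7 to 79.8, Eif2s3y at 69.8 to 77.3, Kdm5d at 40.5 to 46.5 and Uty at 8.27 to 19.6. Female tissue with Y probes lit by their X homologs was argued against by Xist, well above background in 3 of 32 combinations of probe and array. A sex label that differs from the tissue used stays open. No biological explanation was tested.

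Some single genes and lists moved in opposite directions in the genotypes after ENU, which was not tested between samples, since each group holds 1 RNA sample. D17H6S56E-5 was higher by 1.13 log2 in WT and lower in KO (-3.97), a difference of -5.10. Hsd3b5 changed by 1.82 and -1.19 (difference -3.01), Krt23 was 3.22-fold lower and 2.14-fold higher (difference 2.79), and Prelid2 by 1.97 and -2.33 (difference -4.30). The male-predominant list had medians of 0.24 in WT and -0.39 in KO, with an interaction median of -0.95.

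Others had opposite genotype differences on vehicle and after ENU, also not tested. Ppp1r3g differed by -2.86 on vehicle and 2.63 after ENU (difference 5.49), Myom1 by -1.61 and 1.28 (difference 2.89) and Dbp by -1.98 and 1.85 (difference 3.82). Prelid2 differed by 1.35 and -2.95, Ptgds by 1.25 and -2.51 (difference -3.76) and Slc41a2 by 1.04 and -2.29 (difference -3.32). Cholesterol synthesis genes had medians of 0.08 and -1.54, with an interaction median of -1.40; the vehicle value turned negative with all probes averaged and with median centring.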

How the results depend on the processing

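Median centring and the fit of the average KO effect over 4 RNA samples and the average ENU effect over 4 RNA samples, with its alternatives, were chosen after seeing the data, and the other alternatives before. Of the named gene results under all alternatives, 2239 kept direction and side of the threshold, 1 was weaker (Dicer1 ENU_KO, -0.08 with all probes averaged) and 1 reversed; of the list shifts, 2679 moved by less than the spread between arrays, 836 by more and 13 reversed. Most named genes were picked as large differences beyond array noise, the same threshold, so most could hardly change side. A replicate block, an intensity trend and a fit of only the groups compared leave the differences as they are. Each moved 0 results by more than 1.5 times. Direction and threshold also hide changes of size. Normexp moved 59 of 136 named gene results by more than 1.5 times, all toward 0, and averaging all probes moved 19, of which 13 shrank. Of list members at least 2-fold different in KO on vehicle, normexp moved 136 of 406 that far, 11 of them to the other sign, and quantile normalization 48. For ENU in WT normexp moved 78 of 254, 5 to the other sign. Except where stated, the cause was not tested.

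Asking for at least 2-fold lowered the counts by construction: genes ENU against vehicle in WT 2106, genes ENU against vehicle in KO 1579, genes KO against WT on vehicle 4955, genes KO against WT after ENU 5324, genes interaction of genotype and ENU 1514, genes average ENU effect 1518 and genes average KO effect 4973. Averaging a and b to 4 RNA samples gave 5844 for genotype and 0 for ENU; model and error term change with the number of samples. The average ENU effect over 4 RNA samples was 3 genes with normexp and 3 with probes above background on all arrays. Of the gene list tests on 8 arrays, 164 of 294 were called and 29 with an estimated correlation.

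Leaving out 1 array at a time gave 11548 to 11966 genes for ENU in WT, 10367 to 12175 for ENU in KO, 13610 to 14740 for KO on vehicle, 13667 to 14673 for KO after ENU, 8153 to 9201 for the interaction, 12552 to 13225 for the average ENU effect and 14997 to 15644 for the average KO effect. These counts measure array noise. The agreement of independent fold changes lay at 0.396 to 0.463 for ENU and 0.779 to 0.805 for genotype, below 0.5045 and 0.836 with all arrays. Leaving out an array also loosens the filter, since its group then needs only 1 array well above background, so these ranges are not the effect of single arrays alone. With normexp the agreement was 0.556 and 0.853, with no filter on dim probes 0.397 and 0.757, and with probes above background on all arrays 0.578 and 0.848. For Dicer1 in every sample, as the difference of KO from WT over both treatments, probe A_51_P483059 moved to -0.34 with quantile normalization and probe A_51_P333060 to -1.14 with normexp.

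With the replicate letter as a block, genes KO against WT on vehicle numbered 14395. Arrays with the same letter did not deviate together (correlations of -0.02 to 0.11), so the letters are no pairing. For genes average KO effect the slide as a block gave 13408; for ENU it was not run, since slide and ENU coincide, and seed matches were not run for want of transcripts.

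Reversals were these. Afp ENU_KO was -0.005 without KO vehicle array b, in a leave-one-out range of -0.005 to 0.072. With normexp the interaction medians were 0.15 for DNA replication and S phase and 0.35 for G2 and mitosis, and list shifts were -0.003 for T cell markers (KO on vehicle) and -0.12 for B cell markers (ENU in WT). For KO on vehicle, cholesterol synthesis was -0.067 with all probes averaged and -0.15 with median centring, acute phase 0.31 with quantile normalization, and NRF2 targets -0.016 without a filter, -0.016 without KO ENU array b, -0.003 without KO vehicle array a (leave-one-out range -0.016 to 0.052) and -0.20 with median centring. For ENU in KO, erythroid markers were -0.15 without a filter and -0.031 without KO ENU array a (range -0.031 to 0.387). Signal over background limits the folds of 1799 genes for KO on vehicle and 1159 for ENU in WT to bounds.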

Other observations

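The gene groups of this part were fixed before the data were examined, and the fit of the 4 RNA samples was chosen after seeing them. Drug and steroid handling split in KO. Of 23 xenobiotic metabolism genes 5 rose and 9 fell: the sulfotransferase Sult2a2 was at least 104-fold higher on vehicle and Cyp2b10, an inducible P450, 3.91-fold higher, while Cyp2c54 and Cyp2c37 were 9.88-fold and 8.45-fold lower. Glucose genes split too, with 3 of 17 rising and 5 falling; the hexokinase Hk2 was 8.14-fold higher on vehicle and 3.27-fold after ENU, and the pyruvate kinase Pkm 3.31-fold and 2.98-fold higher, while the glucose-releasing phosphatase G6pc was 2.34-fold and 2.20-fold lower. In lipid storage 5 of 14 rose and 3 fell, with the lipoprotein receptor Vldlr 8.32-fold and 10.2-fold higher and Fitm1 10.8-fold and 17.0-fold lower. Of 23 NRF2 targets 5 rose and 4 fell, including Gsta2 (4.66-fold and 2.72-fold higher) and the glutathione synthesis subunit Gclc (2.29-fold and 4.40-fold lower). Among 27 acute phase genes 3 rose and 5 fell, with Lcn2 15.5-fold and 8.88-fold higher and Saa4 4.18-fold and 6.71-fold lower. Of 21 heat shock and ER stress genes 1 rose and 5 fell, with Asns 7.34-fold and 2.44-fold higher and Chac1 3.29-fold and 10.3-fold lower, and of 18 clock genes 0 rose and 3 fell, with Cry1, a clock repressor, 2.14-fold and 1.68-fold lower. Of 17 immediate early genes 7 rose and 0 fell, with Ier3 at least 13.8-fold and Egr2 at least 9.09-fold higher on vehicle. Of 33 interferon genes 13 rose and 0 fell, with Cxcl10 10.4-fold and 5.90-fold higher. Adjusted over the list alone, the numbers that rose and fell were 5 and 9 for xenobiotic metabolism, 6 and 8 for glucose genes, 5 and 3 for lipid storage, 6 and 5 for NRF2 targets, 3 and 5 for acute phase, 1 and 5 for heat shock, 0 and 0 for the clock, 9 and 0 for immediate early and 16 and 1 for interferon genes. With an estimated correlation, the adjusted p of these lists was 0.447 for immediate early genes and 0.562 to 0.941 for the others. Medians of the immediate early and interferon lists lay above all random lists in both pairs. The other percentiles on vehicle and after ENU were 0.04 and 73.3 for xenobiotic metabolism, 91.6 and 44.3 for glucose genes, 99.6 and 61.9 for lipid storage, 99.8 and 91.4 for NRF2 targets, 99.4 and 12.6 for acute phase, 0.38 and 26.7 for heat shock and 0 and 43.4 for the clock. Normexp gave 2.72-fold and 2.01-fold for Hk2, 4.06-fold and 5.57-fold for Vldlr, 10.4-fold for Fitm1 and 6.15-fold for Chac1 after ENU, and on vehicle 31.2-fold for Sult2a2, 4.07-fold for Ier3 and 1.69 log2 for Egr2, below their bounds. Quantile normalization gave -0.55 and -0.45 log2 for G6pc and 2.71-fold for Saa4 on vehicle.

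Lymphoid markers rose in part: 9 of 15 T cell markers rose and 2 fell, 4 of 10 B cell and plasma cell markers and 4 of 8 natural killer markers rose, with Cd8a at least 7.29-fold higher on vehicle and the plasma cell gene Jchain 6.44-fold and 7.92-fold higher. With dim genes at their bounds the T cell median on vehicle was 0.02 in place of 0.98, and it turned to -0.00 with normexp. Of 8 erythroid markers 3 fell and 1 rose, with the heme synthesis gene Alas2 8.59-fold and 11.9-fold lower. Of 9 platelet markers 1 rose and 2 fell, of 9 pancreatic acinar markers 1 rose and 2 fell, and of 4 adipocyte markers 1 rose and 1 fell; Cfd, the adipsin gene, was at least 68.6-fold lower in KO on vehicle. Adjusted over the list alone, 5 B cell and 2 platelet markers rose, and the other counts of this paragraph were the same; the adjusted p was 0.447 with an estimated correlation for the T, B and natural killer cell markers and 0.573 to 0.719 for the other 4 sets. After ENU the metallothioneins Mt1 and Mt2 were 13.5-fold and 13.8-fold lower in WT and 14.6-fold and 15.2-fold lower in KO; with all probes averaged Mt1 was 6.29-fold and 7.12-fold lower. The heme oxygenase Hmox1 differed by -1.58 and -3.65 log2, and the female-predominant gene Cyp2a4 was 4.38-fold lower in WT. H2-Eb1 stood apart from the other MHC class II genes in KO, 6.71-fold lower after ENU, where H2-Aa was 3.79-fold higher; these ENU values are of 1 RNA sample against 1. Among random lists the medians in KO lay at percentiles 98.8 and 99.9 for T cell, 99.1 and 96.0 for B cell, 92.9 and 98.6 for natural killer, 0 and 28.4 for erythroid, 61.5 and 95.7 for platelet, 2.92 and 9.09 for acinar and 7.55 and 27.1 for adipocyte markers. With normexp Cd8a was 3.04-fold higher and Cfd 17.0-fold lower in KO on vehicle, both under their bounds.

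The split of the 4 RNA samples by genotype alone gave 2120 called genes, by treatment alone 0 (limma; 481 at an unadjusted p under 0.05) and by the crossed grouping 0 (23 at an unadjusted p under 0.05). These are all 3 splits of 4 samples into 2 against 2, too few for a share under 0.05.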
